A study of Mus musculus with 10 samples.

How the data were processed

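RNA from 10 mouse samples was measured by RNA sequencing, 5 labelled IL6 shRNA1 (genotype label: IL6 knockdown) and 5 labelled control shRNA, a non-mammalian sequence in the pLKO.1-puro vector. The labels describe total RNA isolated with RNeasy columns and libraries made with the NEBNext Ultra II RNA kit, and they give 1 batch. The labels name FastQC 0.11.9, Trim Galore 0.6.6, STAR 2.7.0f, SAMtools 1.11, Subread 1.6.4 with featureCounts and R 4.0.4, with the mouse builds mm10 and GRCm38. The strand setting, the annotation release, the handling of reads that map to several genes and the tool that made the FPKM values are not given in the sources used here.

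The deposited count table from the authors holds raw whole-number counts per gene, with no normalization, for 55385 genes and 1 column per sample. The deposited FPKM table from the authors holds the same genes as FPKM, scaled by the length of the gene model and by the column total. Each FPKM value equalled the count divided by a fixed gene length and by the column total, with a largest relative deviation of 9.4e-07. No sample column was left out. In the table, 3 genes carried no symbol and 217 entries shared a symbol with another. Gene positions came from the deposited count table. The GENCODE annotation release M21 held 99.6% of the gene identifiers and served to look up missing symbols and the GC content of transcripts.

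Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group at its defaults (minimum count 10) were kept, which left 15064 genes, and libraries were scaled with TMM factors. Dispersions were estimated by estimateDisp, and a quasi-likelihood model with an intercept and the group (glmQLFit with robust=TRUE, glmQLFTest) was tested, with p-values adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and a gene that differed at least 2-fold also had an absolute log2 fold change of at least 1. Fold changes are those of the samples labelled IL6 shRNA1 over control, and CPM values are counts scaled to the library size with the TMM factors. Single values per library were compared by an exact two-sided permutation test over all 252 regroupings of 5 against 5, whose smallest p is 0.0079.

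The genes named were set by a rule. Il6 came first. Next came the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 5 CPM, groups that did not overlap, and a symbol that is not that of a predicted or unnamed model. For each gene list, up to 4 called members with the smallest p followed, and then Il6ra, Il6st, Socs3, Stat3, Arid1a, Pik3ca, Cdkn1a, Mki67, Ptprc, Pecam1, Epcam, Krt8 and Vim. Members of the lists of technical signs and of other cell types were named where they passed or as the most abundant. Of the genes this rule takes, 1 is not reported here. Other genes named were chosen after their values were seen, and the text says so.

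A total of 29 gene lists was tested with camera of limma 3.58.1 at its preset correlation of 0.01 on voom values, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The lists were the IL-6 cytokine family, STAT3 response genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, MHC class I antigen presentation, DNA replication and S phase, mitosis, mesenchymal and EMT genes, extracellular matrix, epithelial and Mullerian tumour markers, FOXO targets, PI3K, AKT and mTOR components, SWI/SNF subunits, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ATF4 and unfolded protein response, p53 targets, angiogenic factors, apoptosis regulators, stem cell markers, Wnt and Notch targets, immediate early genes, mitochondrial genome, ribosomal proteins, leukocytes, endothelium, fibroblasts and pericytes, and muscle, fat, skin and blood. The symbols Ctgf and Cyr61 were found under their current names Ccn2 and Ccn1. The score of a list in a library was the mean over its tested members of log2 CPM minus the gene's mean over all libraries. The level of a chromosome in a library was the median of the same centred values, for the 20 chromosomes with at least 100 tested genes.

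The groups, tests, gene lists, named-gene rule and first set of alternatives were fixed before the data were examined. The alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma voom, a fit without robust dispersion, the number in the sample titles as a block, an adjusted p under 0.01, the deposited FPKM values with pseudocounts of 1 and 0.1, and the omission of each library in turn. Added after the data were seen were the leukocyte score as a covariate, the omission of the 3 libraries farthest from the rest on the first principal component, the omission of the genes of chromosomes 1 and 6, and limma on the chromosome values. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for table handling and plots.

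The model was tested on simulated data of the same size, 15064 genes in 5 against 5 samples. It recovered 41 of 67 genes changed 1.5-fold, 58 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 7.3% of its calls were false. With no change simulated it made 0 calls. The changed genes were drawn from those with a mean of at least 5 CPM, and each gene was simulated independently. These shares therefore do not cover genes as low as Il6 or genes that vary together between libraries. A simulated rise of chromosome 9 by 0.3 on the log2 scale was estimated at 0.29.

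Totals were 17905397 to 22682346 counts per library, and the common biological coefficient of variation was 23%. Intervals are at the 95% level. The labels do not say whether the 5 samples of a group are separate animals, tumours or cultures, so the p-values measure only the spread between samples. With 1 shRNA against Il6, an effect of the target cannot be separated from any other difference between the 2 cell populations.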

Results

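Gene expression was measured in 10 RNA samples from a mouse ovarian tumour line with mutations in Arid1a and Pik3ca. The line is written APV245 in the sample titles and APC245 in the description of the design. A lentiviral shRNA against Il6 (IL6 shRNA1) was the label of 5 samples, and a non-mammalian shRNA control was the label of the other 5. The sample labels describe cells in DMEM culture, while the design describes tumours grown under the skin. The samples labelled IL6 shRNA1 had totals of 17905397 to 19934278 counts and the control samples 18224751 to 22682346. The comparison asks what depletion of IL6 does to gene expression in these samples, in which markers of leukocytes and other cell types were also counted.

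Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) encodes the cytokine interleukin-6, and its mRNA was not lower in the libraries labelled IL6 shRNA1. It stood at 1.73 ± 0.41 CPM in them and at 1.26 ± 0.64 CPM in the control libraries (SD, n = 5 each). The log2 fold change was 0.44 ± 0.36 (SE), with a 95% interval from -0.36 to 1.24 and an adjusted p of 0.44. An exact permutation test of the CPM values gave p = 0.21. The values rest on 9 to 48 counts per library, and the largest fall inside the interval was 22%. Because Il6 was not lower, the groups are named by their labels throughout, and directions are those of the libraries labelled IL6 shRNA1 relative to control. With the leukocyte score of each library as a covariate, a fit added after the data were seen, the Il6 log2 fold change was -0.48 ± 0.34 (SE; adjusted p = 0.64). Among the receptor and signalling genes, Il6ra was at 25.7 against 22.1 CPM (adjusted p = 0.34), Stat3 at 312 against 336 CPM (adjusted p = 0.43), and the STAT3 feedback gene Socs3 at 79.6 against 62.4 CPM (adjusted p = 0.12).

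**Figure D1:**
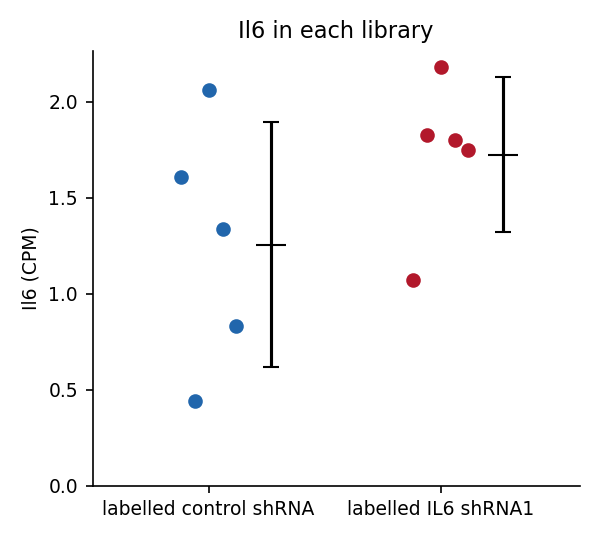
Il6 mRNA in CPM (vertical axis) in the 5 libraries labelled control shRNA (blue) and the 5 labelled IL6 shRNA1 (red), 1 point per library, with the group mean ± SD as the black bar. The means were 1.26 and 1.73 CPM, and the groups overlap.

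Among called genes with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not that of a predicted or unnamed model, the largest rise was that of Hoxb9, a homeobox transcription factor gene (chromosome 11, 96271457 to 96276595), at 19.8 ± 3.61 CPM in the libraries labelled IL6 shRNA1 against 0.993 ± 0.65 CPM in control (SD, n = 5 each; log2 fold change 4.29 ± 0.39 SE, adjusted p = 0.00044). Sostdc1, a secreted antagonist of BMP and Wnt signalling, rose from 5.07 ± 1.52 to 29.3 ± 5.3 CPM, and Igf2bp1, an mRNA-binding protein gene, from 5.88 ± 1.27 to 32.4 ± 3.14 CPM. The transcription factor genes Pax3 (on chromosome 1; log2 fold change 2.09 ± 0.16 SE) and Bcl11b (1.57 ± 0.21) rose as well, as did Tent5c (1.67 ± 0.24), a poly(A) polymerase gene, and the deubiquitinase gene Uchl1 (1.46 ± 0.30). Genes known from immune cells were in this group too: Arg1, which encodes arginase 1 (1.88 ± 0.39), the cytokine gene Il1b (1.77 ± 0.37) and Cd83 (1.75 ± 0.43). Under the same limits the largest fall was that of Trh, the precursor of thyrotropin-releasing hormone (chromosome 6, 92242061 to 92244650), at 1.66 ± 1.03 CPM against 27.9 ± 9.1 CPM (log2 fold change -4.07 ± 0.40 SE, adjusted p = 0.00081). The anion transporter gene Slc26a7 followed with a log2 fold change of -4.06 ± 0.84 (SE). Then came the X-linked homeobox gene Rhox5 (-2.81 ± 0.40) and Padi3, a peptidylarginine deiminase gene (-2.73 ± 0.21). Dlg2, a synaptic scaffold gene (-2.50 ± 0.32), the netrin receptor gene Unc5c (-2.43 ± 0.52) and the Wnt ligand gene Wnt16 (on chromosome 6; -2.33 ± 0.53) fell too. The last of the 10 were the matrix protein gene Spon2 (-2.24 ± 0.37), Plac1 (-2.13 ± 0.42) and the guanylate cyclase subunit gene Gucy1a1 (-1.99 ± 0.46). Adjusted p-values of these 20 genes were 0.03 or lower, and their groups did not overlap.

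**Figure D2:**
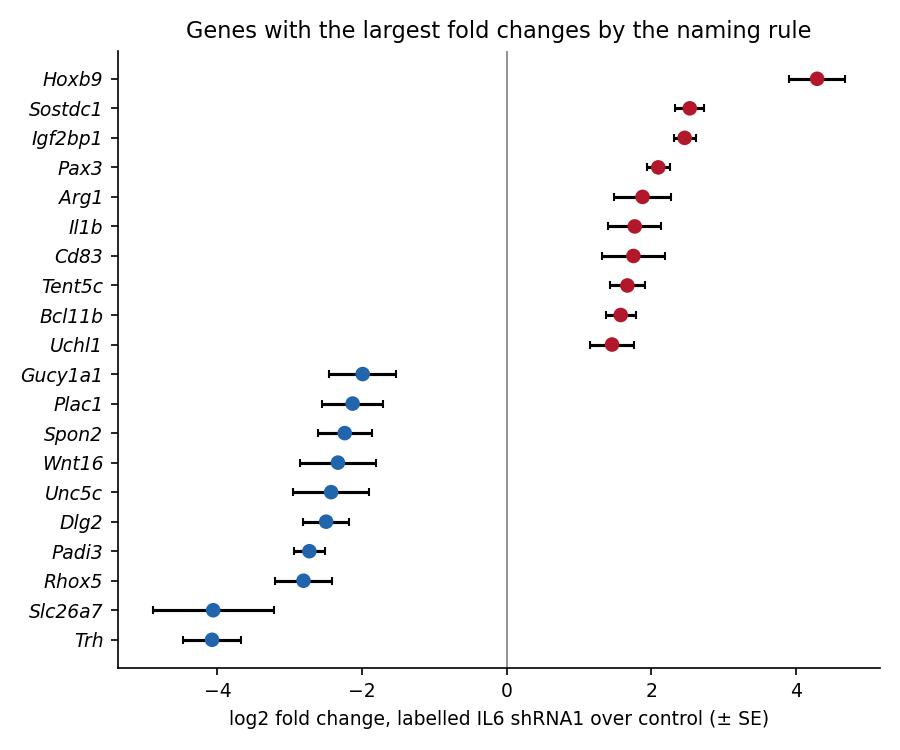
Log2 fold change, libraries labelled IL6 shRNA1 over control (horizontal axis), of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) by the naming rule; points are estimates from 5 against 5 libraries and bars are ± SE. Hoxb9 stands at 4.29 and Trh at -4.07.

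Of 15064 genes tested, 847 were higher and 928 lower in the libraries labelled IL6 shRNA1, 1775 in all. A difference of at least 2-fold was found for 373 genes, 242 higher and 131 lower. The groups did not overlap for 1310 of the called genes, and for 10.9% of all genes tested against 0.79% by chance. The first principal component held 54.3% of the variance and differed between the groups (exact permutation p = 0.032). IL6 shRNA1 library 5 lay at 65.2 on it, control libraries 2 and 5 at -64.9 each, and IL6 shRNA1 library 1 at -21.4. Without the 3 libraries farthest out on it (IL6 shRNA1 library 5, control libraries 2 and 5) 212 genes were called, 203 of them among the 1775, and with the leukocyte score as a covariate 113 were called, 111 of them among the 1775. That score was itself higher in the libraries labelled IL6 shRNA1 (mean 0.48 against -0.48), so it shares variance with the group. A call lost with that covariate therefore does not show that leukocytes account for the gene. The call was lost with that covariate for Arg1 (adjusted p = 0.28), Il1b (0.31), Cd83 (0.38), Uchl1 (0.31), Slc26a7 (0.24), Rhox5 (0.061), Unc5c (0.26), Wnt16 (0.41), Spon2 (0.11), Plac1 (0.12) and Gucy1a1 (0.31). It was kept in every alternative that gave a value for Hoxb9, Sostdc1, Igf2bp1, Pax3, Tent5c, Bcl11b, Trh, Padi3 and Dlg2. Of the genes named for their lists, Twist1 and Hsd17b7 kept the call with the covariate. Without the 3 farthest libraries Twist1, Hsd17b7, Irs2, Aldoc, Sdhc, Btg2, Pmaip1, Mdk, Bcl2 and Notch3 kept it, with Rhox5 and Spon2, whereas it was lost for Arg1 (adjusted p = 0.12), Il1b (0.067), Cd83 (0.083), Uchl1 (0.08), Slc26a7 (0.14), Unc5c (0.19), Wnt16 (0.15), Plac1 (0.11) and Gucy1a1 (0.23). Of all 102 called genes named here or held in the lists, 52 kept the call in each omission of a single library. Single libraries moved the count too: it was 2774 without IL6 shRNA1 library 1, 869 without library 2, 1024 without library 3, 1154 without library 4 and 989 without library 5. Without control library 2 it was 875, and without control library 5 it was 864. The 2-fold count of 373 became 759, 217, 220 and 209 without IL6 shRNA1 libraries 1, 2, 3 and 5, and 616, 220 and 189 without control libraries 1, 2 and 5. Cd83 lost its call without IL6 shRNA1 libraries 2 to 5 (adjusted p = 0.066, 0.063, 0.052 and 0.066) and control libraries 4 and 5 (0.053 and 0.073). Wnt16 lost it without IL6 shRNA1 libraries 3, 4 and 5 (0.054, 0.052 and 0.053) and control library 2 (0.055). Gucy1a1 lost it without IL6 shRNA1 libraries 2, 3 and 5 (0.056, 0.052 and 0.055) and control libraries 2 and 5 (0.057 and 0.062).

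Lists of immune cell genes and of the response to interferon shifted up in the libraries labelled IL6 shRNA1 by camera at its preset correlation. Of 25 leukocyte markers tested, 9 were higher, 0 lower and 16 not called, with 14 higher when adjusted over the list alone. Among them, the complement genes C1qa (467 ± 125 against 204 ± 81.2 CPM; SD, n = 5) and C1qb (409 ± 101 against 174 ± 70.3 CPM), the receptor gene of macrophage growth factor Csf1r (276 ± 46.2 against 151 ± 44.5 CPM) and the lysozyme gene Lyz2 (671 ± 101 against 409 ± 99.7 CPM) rose. The most abundant member was Cd74, the MHC class II invariant chain gene, at 2240 ± 769 against 858 ± 433 CPM. Ptprc, the pan-leukocyte CD45 gene on chromosome 1, was at 106 against 58.3 CPM and was not called (adjusted p = 0.10). The list shifted up by camera (median log2 fold change 0.94, adjusted p = 1.8e-07; adjusted p = 0.55 with an estimated correlation). All 32 interferon-stimulated genes had positive fold changes with a median of 0.75, although 2 of them, the RNA sensor gene Ddx58 (93.8 against 67.5 CPM) and Xaf1 (38.9 against 23.1 CPM), were called, 30 were not, and 0 were higher when adjusted over the list alone. The list shifted up by camera (adjusted p = 6.7e-10; adjusted p = 0.55 with an estimated correlation). Of 18 genes of MHC class I antigen presentation, 1 was higher, the peptide-trimming enzyme gene Erap1 (89.9 ± 13.2 against 51.4 ± 13.9 CPM), 17 were not called, and 10 were higher when adjusted over the list alone. That list had a median of 0.76 and shifted up by camera (adjusted p = 2.4e-06; adjusted p = 0.55 with an estimated correlation). The H2 genes in these lists have close paralogs. Of 26 inflammatory cytokines and NF-kB targets, 5 were higher and 21 not called, with 10 higher when adjusted over the list alone. Those with the smallest p were Il1b, Il1a (log2 fold change 1.62), Ptgs2 on chromosome 1 (the prostaglandin synthase COX-2; 227 against 98.8 CPM) and the chemokine gene Cxcl16 (118 against 52.1 CPM). That list had a median of 0.49 and shifted up by camera (adjusted p = 1.2e-05; adjusted p = 0.55 with an estimated correlation). The leukocyte score was 0.48 ± 0.38 against -0.48 ± 0.68 (SD, n = 5; exact permutation p = 0.024, adjusted over the 29 lists 0.086). With that score as a covariate, the interferon list (camera adjusted p = 0.40) and the MHC class I list (0.98) were no longer called and their direction turned down. The NF-kB list lost its call too (camera adjusted p = 0.82). So did the leukocyte list (0.31), but by construction, since the covariate is the mean of its own members, so that loss tells nothing. Csf1r lost its call without IL6 shRNA1 libraries 2 to 5 (adjusted p = 0.058, 0.051, 0.054 and 0.06) and without control library 5 (0.055).

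**Figure D3:**
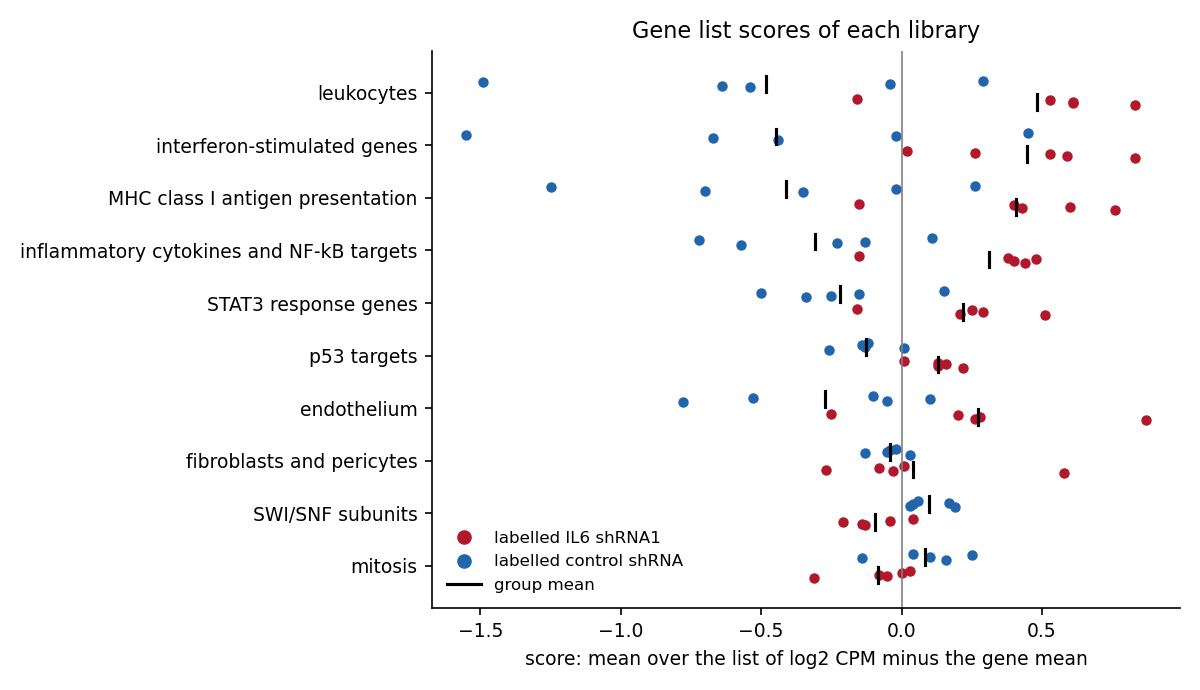
Score of 10 gene lists (mean over the list of log2 CPM minus the gene mean, horizontal axis) in each library, with red points for the 5 libraries labelled IL6 shRNA1, blue points for the 5 control libraries and black bars for the group means. The leukocyte score averages 0.48 in the first group and -0.48 in the second, and the interferon score 0.45 and -0.45.

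Among 16 genes of the IL-6 cytokine family, 3 were higher, 1 was lower and 12 were not called, with 4 higher and 2 lower when adjusted over the list alone. The cytokine genes Osm (2.40 ± 0.33 against 0.764 ± 0.45 CPM; SD, n = 5), Ebi3 (2.67 against 1.05 CPM) and Lif (20.3 against 13.7 CPM) were higher. Il6st, the gene of the shared signalling receptor gp130, was lower (279 ± 36.5 against 374 ± 37.8 CPM). The family did not shift as a set (camera adjusted p = 0.36). Of 25 STAT3 response genes, 3 were higher and 22 not called, with 3 higher when adjusted over the list alone: the cyclin gene Ccnd1 (64.8 against 41.8 CPM), the kinase gene Pim1 (50.9 against 31.7 CPM) and Junb (216 against 157 CPM). The list shifted up by camera (median 0.30, adjusted p = 0.0043; adjusted p = 0.55 with an estimated correlation). Without the 3 farthest libraries its adjusted p was 0.14, and with the leukocyte covariate 0.82. Of 20 immediate early genes, which respond within an hour to handling or serum, 7 were higher and 13 not called, with 9 higher when adjusted over the list alone. Btg2 on chromosome 1 (136 against 63.0 CPM), Klf6 (157 against 110 CPM), Klf2 (38.5 against 26.7 CPM) and Dusp1 (28.5 against 15.2 CPM) had the smallest p. This list shifted up by camera (median 0.40, adjusted p = 0.00067; adjusted p = 0.55 with an estimated correlation).

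Genes of growth arrest and cell death were called in part. Of 21 p53 targets, 5 were higher and 16 not called, with 6 higher when adjusted over the list alone. They were Btg2 and the epoxide hydrolase gene Ephx1 (16.7 against 11.6 CPM), both on chromosome 1, with Pmaip1, which encodes the BH3 protein NOXA (28.8 ± 3.19 against 13.3 ± 4.79 CPM; SD, n = 5), Ccng1 (233 against 163 CPM) and the cell cycle inhibitor gene Cdkn1a (130 against 94.4 CPM, adjusted p = 0.0495). The list shifted up by camera (median 0.09, adjusted p = 0.043; adjusted p = 0.55 with an estimated correlation). It did not without IL6 shRNA1 libraries 3, 4 and 5 (adjusted p = 0.054, 0.055 and 0.051), control libraries 1 and 3 (0.088 and 0.072), or the genes of chromosomes 1 and 6 (0.16). Of 24 apoptosis regulators, 5 were higher and 19 not called, with 5 higher and 2 lower when adjusted over the list alone. Of the 4 with the smallest p, the survival gene Bcl2 (12.1 against 6.19 CPM) and the initiator caspase gene Casp8 (92.9 against 74.0 CPM) lie on chromosome 1, and Pmaip1 and Bcl2a1a (8.23 against 4.36 CPM), which has close paralogs, do not. The list shifted up by camera (median 0.11, adjusted p = 0.03; adjusted p = 0.55 with an estimated correlation), but not without control library 4 (adjusted p = 0.061), the genes of chromosomes 1 and 6 (0.18) or the 3 farthest libraries (0.053), nor with the leukocyte covariate (0.53).

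Lists that shifted down had small medians. Of 24 SWI/SNF subunits, the family of the tumour suppressor Arid1a, 2 were lower and 22 not called, with 1 lower when adjusted over the list alone. They were Smarcc2 (94.6 ± 9.21 against 121 ± 8.15 CPM; SD, n = 5) and Bcl7a (12.6 against 19 CPM), and 1 of the 24 had a positive fold change. The list shifted down by camera (median -0.19, adjusted p = 0.00069; adjusted p = 0.55 with an estimated correlation), but not with the leukocyte covariate (adjusted p = 0.19). Arid1a itself was at 81.7 against 87.5 CPM (adjusted p = 0.44). Of 30 mitosis genes, 1 was lower, the kinesin gene Kif2c (28.5 against 36.6 CPM), 29 were not called, and 0 were lower when adjusted over the list alone. The proliferation marker Mki67 was at 228 against 259 CPM (adjusted p = 0.51). The list shifted down by camera (median -0.19, adjusted p = 0.0019; adjusted p = 0.76 with an estimated correlation), but not with the leukocyte covariate (adjusted p = 0.72) or without the 3 farthest libraries (0.46). Of 30 genes of DNA replication and S phase, 1 was higher, the helicase subunit gene Mcm3 on chromosome 1 (103 against 86.2 CPM), 29 were not called, and 0 were called when adjusted over the list alone. The list nevertheless shifted down by camera (median -0.12, adjusted p = 0.045; adjusted p = 0.82 with an estimated correlation). It did not without IL6 shRNA1 libraries 1 and 5 (adjusted p = 0.25 and 0.27) or control libraries 1, 2, 3 and 5 (0.057, 0.11, 0.12 and 0.051), nor without the 3 farthest libraries (0.65), with the leukocyte covariate (0.20) or with a filter of 1 CPM (0.065). Of 27 hypoxia and glycolysis genes, 3 were lower and 24 not called, with 3 lower when adjusted over the list alone. They were the glycolytic enzyme genes Aldoc (18.5 ± 2.43 against 29.9 ± 0.93 CPM), Tpi1 on chromosome 6 (768 against 1040 CPM) and Pfkl (242 against 321 CPM). The list shifted down by camera (median -0.08, adjusted p = 0.03; adjusted p = 0.82 with an estimated correlation), but not without IL6 shRNA1 library 4 (adjusted p = 0.68), control libraries 4 and 5 (0.085 and 0.051) or the genes of chromosomes 1 and 6 (0.18), nor with the leukocyte covariate (0.53).

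Markers of cell identity were called in part. Of 20 epithelial and Mullerian tumour markers, 2 were higher and 18 not called, with 6 higher when adjusted over the list alone: the tight junction gene Ocln (1.17 ± 0.46 against 0.297 ± 0.05 CPM; SD, n = 5) and the mesothelial marker Upk3b (120 ± 8.68 against 58.9 ± 27.6 CPM). Epcam was at 4.17 against 2.81 CPM (adjusted p = 0.23) and Krt8 at 71.0 against 53 CPM (adjusted p = 0.38). This list shifted up by camera (median 0.47, adjusted p = 0.0061; adjusted p = 0.55 with an estimated correlation), but not without the 3 farthest libraries (adjusted p = 0.059). Of 31 mesenchymal and EMT genes, 4 were higher, 2 were lower and 25 not called, with 4 higher and 3 lower when adjusted over the list alone. The paralogous transcription factor genes moved apart: Twist1 fell (26.7 ± 2.66 against 57.3 ± 12 CPM) and Twist2 on chromosome 1 rose (1.04 ± 0.16 against 0.352 ± 0.15 CPM). The N-cadherin gene Cdh2 was lower (135 against 195 CPM), Tgfbi was higher (754 against 552 CPM), and the intermediate filament gene Vim was at 2680 against 2580 CPM (adjusted p = 0.71). The list did not shift as a set (camera adjusted p = 0.78), and its median of -0.04 and mean of 0.05 differed in sign. Of 30 extracellular matrix genes, 2 were higher, 3 lower and 25 not called, with 2 higher and 3 lower when adjusted over the list alone. The small proteoglycan genes Lum (441 ± 126 against 860 ± 122 CPM) and Dcn (511 ± 94.3 against 783 ± 111 CPM) and the basement membrane gene Col4a1 (359 against 652 CPM) were lower, and Thbs1 (3100 against 2010 CPM) was higher. The list did not shift as a set (median -0.06, camera adjusted p = 0.93). Lum and Dcn are also 2 of the 17 fibroblast and pericyte markers, of which 1 was higher, the smooth muscle myosin gene Myh11 (9.38 against 4.66 CPM), 2 lower and 14 not called, with 2 higher and 3 lower when adjusted over the list alone. That list did not shift (camera adjusted p = 0.98; median -0.06, mean 0.10).

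None of the next 5 lists, of signalling genes and stem cell markers, shifted as a set. Of 15 Wnt and Notch targets, 1 was higher, 3 lower and 11 not called, with 2 higher and 3 lower when adjusted over the list alone. The receptor gene Notch3 (24.8 ± 5.82 against 51.0 ± 9.81 CPM; SD, n = 5) and the Notch target genes Heyl (21.8 against 36.3 CPM) and Hey1 (82.9 against 112 CPM) were lower, and the Notch target gene Hes1 (27.2 against 19.9 CPM) was higher. The list did not shift as a set (camera adjusted p = 0.28). Of 20 angiogenic factors, 2 were higher, 4 lower and 14 not called, with 3 higher and 5 lower when adjusted over the list alone. Mdk, a heparin-binding growth factor gene (41.1 ± 8.35 against 107 ± 25.3 CPM), Angpt1 (40.4 against 65.0 CPM) and Vegfb (20.7 against 30.3 CPM) were lower, while Vegfc (27.9 against 18.8 CPM) was higher. The list did not shift (camera adjusted p = 0.93, direction down, with a positive median of 0.09). Of 23 PI3K, AKT and mTOR components, 1 was higher and 3 were lower, as also when adjusted over the list alone, and 19 were not called. Pik3r2 (91.4 ± 7.09 against 131 ± 15.4 CPM), Tsc2 (58.5 against 71.4 CPM) and Akt2 (139 against 163 CPM) were lower, the phosphatase gene Phlpp1 on chromosome 1 (34.8 against 23.4 CPM) was higher, and Pik3ca was at 163 against 188 CPM (adjusted p = 0.083). The list did not shift (camera adjusted p = 0.56). Of 19 FOXO targets, 1 was higher over all genes and over the list alone, the insulin receptor substrate gene Irs2 (20.5 ± 4.97 against 9.33 ± 2.57 CPM), and 18 were not called. That list did not shift (camera adjusted p = 0.78; median -0.03, mean 0.20). Of 17 stem cell markers, 3 were lower and 14 not called, with 4 higher and 4 lower when adjusted over the list alone. The transporter gene Abcg2 (48.8 against 60.9 CPM) and the histone methyltransferase gene Ezh2 (64.8 against 85.9 CPM) lie on chromosome 6, and Bmi1 (81.1 against 101 CPM) does not. The list did not shift (median 0.24, camera adjusted p = 0.78).

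The remaining metabolic and housekeeping lists, 5 in number, did not shift as sets with all libraries and genes in the fit. Of 27 nuclear genes of oxidative phosphorylation, 3 were higher over all genes and over the list alone, 24 were not called, and the camera adjusted p was 0.26. Among the higher ones were Sdhc (125 ± 5.82 against 99.0 ± 6.18 CPM; SD, n = 5) and Ndufs1 (84.0 ± 5.26 against 68.4 ± 2.53 CPM), both on chromosome 1. Of 25 cholesterol synthesis genes, 2 were higher and 1 lower over all genes and over the list alone, and 22 were not called (camera adjusted p = 0.78). Hsd17b7 on chromosome 1 (68.4 ± 1.85 against 42.2 ± 4.03 CPM) and Msmo1 (89.5 against 73.6 CPM) were higher, and Tm7sf2 (10.2 against 15.8 CPM) was lower. Of 27 genes of the ATF4 and unfolded protein response list, 1 was higher over all genes and over the list alone, the endoplasmic reticulum stress gene Herpud1 (107 ± 14.4 against 68.5 ± 4.46 CPM), and 26 were not called (camera adjusted p = 0.057). That list was called without IL6 shRNA1 libraries 1 and 4 (adjusted p = 0.035 and 0.0087), control library 2 (0.027) or the genes of chromosomes 1 and 6 (0.009), and oxidative phosphorylation without IL6 shRNA1 library 1 (0.013), all at the preset correlation. With an estimated correlation on all libraries the adjusted p was 0.76 for the first list and 0.94 for oxidative phosphorylation. None of 25 ribosomal protein genes was called over all genes or over the list alone (camera adjusted p = 0.59; called without IL6 shRNA1 library 3, adjusted p = 0.02, at the preset correlation; 0.97 with an estimated correlation on all libraries). None of 11 protein genes of the mitochondrial genome was called over all genes or over the list alone (camera adjusted p = 0.78).

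Markers of endothelium, muscle, fat, skin and blood were present. None of 15 endothelial markers was called over all genes or over the list alone, but all 15 had positive fold changes with a median of 0.51, and the list shifted up by camera (adjusted p = 0.00093; adjusted p = 0.62 with an estimated correlation), but not with the leukocyte covariate (adjusted p = 0.72) or without the 3 farthest libraries (0.15). The endothelial adhesion gene Pecam1 was at 62.2 ± 22.7 against 44.0 ± 9.8 CPM (SD, n = 5; adjusted p = 0.18). None of 12 markers of muscle, fat, skin and blood was called over all genes or over the list alone, although all 12 had positive fold changes with a median of 2.77. The skeletal actin gene Acta1, the most abundant of them, was at 1120 ± 1320 against 166 ± 210 CPM, a spread larger than the difference, and at 549 ± 419 CPM without IL6 shRNA1 library 5. That list shifted up by camera (adjusted p = 0.023; adjusted p = 0.76 with an estimated correlation), but not without IL6 shRNA1 library 5 (adjusted p = 0.14) or the 3 farthest libraries (0.33), nor with the leukocyte covariate (0.93). The endothelium score was 0.27 ± 0.40 against -0.27 ± 0.37 (SD, n = 5; exact permutation p = 0.063), and with the leukocyte covariate the difference went from 0.54 ± 0.24 to 0.10 ± 0.28 (SE).

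In all, camera at its preset correlation called 15 of the 29 lists, 11 up and 4 down, and with an estimated correlation it called 0, the lowest adjusted p being 0.55, and 0 at an unadjusted p under 0.05. Fry called 0 lists for a change in 1 direction, 10 at an unadjusted p under 0.05, and 24 for a change in either direction. Fry does not compare a list with the other genes, and 4693 of all 15064 genes had an unadjusted edgeR p under 0.05. The 24 therefore do not show a change particular to these lists. With the leukocyte covariate camera at the preset correlation called 4 lists, all up: extracellular matrix, immediate early genes, epithelial and Mullerian tumour markers, and p53 targets. Without the 3 farthest libraries it called 8, up for leukocytes, interferon-stimulated genes, MHC class I antigen presentation, NF-kB targets, immediate early genes and p53 targets, and down for SWI/SNF subunits and hypoxia and glycolysis.

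The median gene of chromosome 1 was higher and that of chromosome 6 lower in the libraries labelled IL6 shRNA1, with 87.8% of the genes of chromosome 1 and 29.1% of those of chromosome 6 having a positive fold change. Of 917 genes tested on chromosome 1, 268 were called higher and 1 lower. Of 797 on chromosome 6, 216 were called lower and 21 higher. The median level of chromosome 1 was 0.17 ± 0.04 against -0.15 ± 0.01 on the log2 scale (SD, n = 5), a difference of 0.32. For chromosome 6 it was -0.10 ± 0.05 against 0.12 ± 0.04, a difference of -0.22. Both had an exact permutation p of 0.0079, the smallest that 5 against 5 can give, and an adjusted p of 0.04. Chromosomes 10 (-0.05) and 15 (-0.06) had the same p with smaller differences, and all chromosomes other than 1 and 6 lay between -0.11 and 0.02. All 20 segments of 10 Mb on chromosome 1 had a positive median log2 fold change, from 0.16 to 0.46, and all 15 on chromosome 6 a negative one, from -0.29 to -0.03. Off these chromosomes, 558 genes were called higher and 711 lower of 13350. Omitting single libraries left the differences at 0.31 to 0.34 and -0.22 to -0.19. Because the adjusted exact p depends on how many chromosomes reach the smallest p, it was 0.079 without IL6 shRNA1 libraries 1 or 2 and 0.053 without IL6 shRNA1 library 5 or control libraries 1, 2 or 5. With the mean over genes in place of the median the differences were 0.40 (adjusted exact p = 0.079) and -0.09 (0.14). Without the 3 farthest libraries they were 0.30 and -0.18 (adjusted exact p = 0.14 for both). Fewer regroupings are then left and the smallest exact p is larger than 0.0079, so that 0.14 is not evidence of a weaker shift. Limma on the chromosome values of all libraries, added after the data were seen, gave adjusted p = 1.6e-12 for chromosome 1 and 5.7e-08 for chromosome 6. It called 6 chromosomes.

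**Figure D4:**
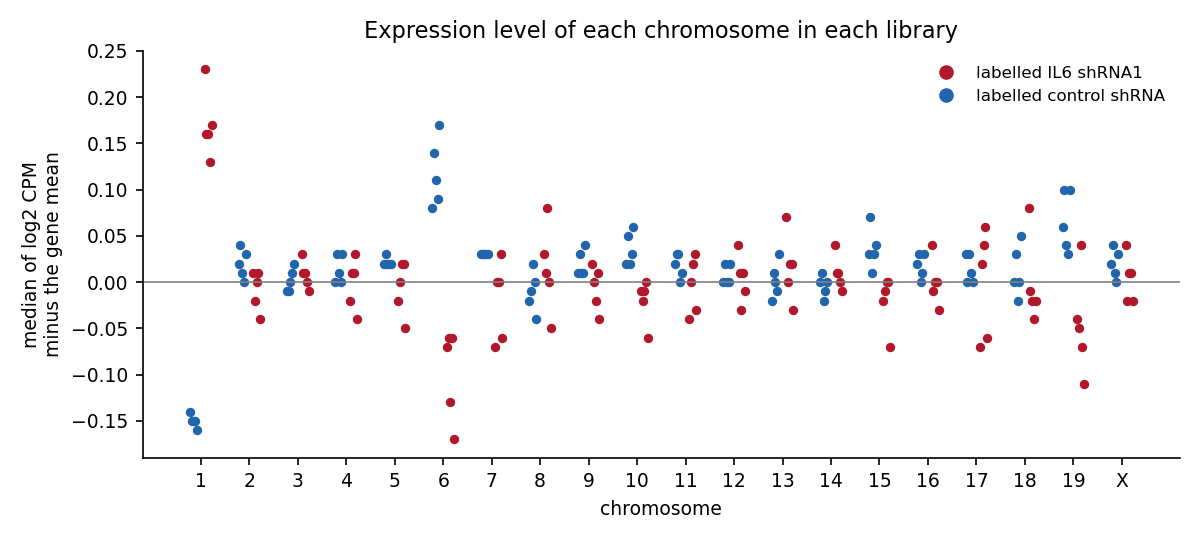
Median over the tested genes of each chromosome (horizontal axis) of log2 CPM minus the gene mean (vertical axis), 1 point per library, red for the 5 libraries labelled IL6 shRNA1 and blue for the 5 control libraries. On chromosome 1 the red points lie from 0.13 to 0.23 and the blue from -0.16 to -0.14, and on chromosome 6 the red points lie from -0.17 to -0.06 and the blue from 0.08 to 0.17.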

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

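Chosen after the results were seen were the tests of a lower share of tumour cells, of too few Il6 counts, of exchanged labels and of the copy number of chromosome 6, and all fits with the leukocyte score as a covariate.

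The first pattern is that the median of chromosome 1 was higher and that of chromosome 6 lower in the libraries labelled IL6 shRNA1. The tables argue against GC content, gene length and expression level, since 0 of 10000 gene sets matched on these reached the median of either chromosome, and against the leukocyte share as the whole of it, since with that score as a covariate chromosome 1 still differed by 0.33 ± 0.02 (SE) and chromosome 6 by -0.18 ± 0.03. A different copy number of chromosome 1 in the 2 cell populations may account for its part, because its 25th percentile of log2 fold change lay 0.33 above that of the other autosomes, so the genes moved as a body. For chromosome 6 this cannot be told apart from a change in part of its genes, as its 25th percentile lay -0.22 from that of the other autosomes and its 75th percentile -0.07. An effect of the knockdown itself was not tested, since the label and the cell population are the same division of the samples.

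The second pattern is that the leukocyte, interferon and MHC class I lists were higher in the libraries labelled IL6 shRNA1 by camera at its preset correlation, though not with an estimated one (adjusted p = 0.55 for each), nor by their scores after adjustment over the lists (exact permutation, adjusted p = 0.086, 0.10 and 0.086). A lower share of tumour cells would raise markers of all other cell types alike, and this cannot be told apart, since the leukocyte score minus the endothelium score was 0.21 ± 0.18 against -0.21 ± 0.57 (SD, n = 5; exact permutation p = 0.16). The leukocyte score minus the fibroblast and pericyte score was 0.44 ± 0.41 against -0.44 ± 0.68 (exact permutation p = 0.04, at or over 0.05 in 7 of 10 omissions of a single library). This difference goes against a like rise of both lists, but it depended on single libraries. It does not decide, because tumour cells may make some of the fibroblast and pericyte markers, which was not tested. The levels of those markers differ widely, with Lum at 441 against 860 CPM and Myh11 at 9.38 against 4.66 CPM. The interferon and MHC class I genes may follow the leukocyte share, because with the leukocyte score as a covariate the difference of the interferon score went from 0.89 ± 0.36 to -0.10 ± 0.12 (SE) and that of the MHC class I score from 0.82 ± 0.31 to -0.02 ± 0.08, though the leukocyte list holds Cd74, which interferon also induces. A change in the leukocytes themselves, by the labelled knockdown or otherwise, stays open.

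The third pattern is that Il6 was not lower in the libraries labelled IL6 shRNA1. Too few counts to see a 2-fold fall in the libraries as a whole is argued against by the 95% interval, whose lower bound was -0.36. That interval does not cover a fall in the tumour cells alone, since markers of other cell types were also counted. For a pair of libraries with exchanged labels, 0 libraries lay on the other group's side of chromosome 1. That cannot decide, because chromosome 1 was singled out for separating the labelled groups. Il6 RNA from leukocytes that differ in share could hide a fall in the tumour cells, and this stays open: with the leukocyte score as a covariate the log2 fold change was -0.48, with an interval from -1.21 to 0.26. Exchange of the labels of both whole groups is not excluded by any value here, and a fall at the protein level, or a knockdown lost as the cells grew, was not tested.

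Other splits of the 10 libraries into 5 and 5 were refitted, 100 of the 126 that exist. The 1775 genes that differed were reached by 1 of them, the real one, and the highest other gave 548. The 373 genes that differed at least 2-fold were likewise reached by the real split only, and the highest other gave 255. Counts this large were therefore rare among divisions of these libraries. Splits that mix the groups hold the group difference as spread, however, which lowers their counts. A chance difference in leukocyte share between the groups is not excluded, as 113 genes were called with the leukocyte score as a covariate. The 2 highest other splits exchanged IL6 shRNA1 library 1 with a control library, and 95 splits gave 0 genes. For the 15 lists chance cannot be excluded, as 21 splits gave as many and the highest other gave 20.

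A single library lay far from the rest of its group in 21 of 282 groups of 5 values, where the gap to the nearest other library exceeded 0.71 of the range; about 1 in 20 such groups, 14 here, would do so by chance. The shares of the range were as follows for IL6 shRNA1 library 1. It was high in Slc26a7 (3.90 CPM, share 0.865), Unc5c (15.7 CPM, 0.816), Plac1 (4.49 CPM, 0.812) and Gucy1a1 (21.5 CPM, 0.738). It was low in Cxcl16 (75.1 CPM, 0.728), C1qa (252 CPM, 0.756) and the score of inflammatory cytokines and NF-kB targets (-0.15, share 0.84). IL6 shRNA1 library 5 was high in Erap1 (113 CPM, 0.793), Tgfbi (930 CPM, 0.806), Ocln (1.96 CPM, 0.712), Irs2 (29.2 CPM, 0.774), Klf6 (189 CPM, 0.806), Epcam (7.89 CPM, 0.874) and Acta1 (3390 CPM, 0.712), and low in Kif2c (24.2 CPM, 0.775). Library 3 of that group was high in Upk3b (135 CPM, 0.823) and low in its total of 17905397 counts (0.795), and library 4 was high in Vegfb (25.1 CPM, 0.755) and Heyl (33.7 CPM, 0.77). Control library 4 was high in Ptgs2 (162 CPM, 0.718), and control library 5 was low in Epcam (1.66 CPM, 0.72).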

How the results depend on the processing

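Chosen after the data were seen were the leukocyte covariate, the omission of the 3 farthest libraries (IL6 shRNA1 library 5, control libraries 2 and 5), the omission of the genes of chromosomes 1 and 6, and limma on the chromosome values. The cause of each change was not tested unless its construction shows it. Of the genes that differ between IL6 shRNA1 and control shRNA, 1775 became 1753 with RLE factors, 1734 with upper quartile factors, 1399 with library size only, 1225 with no filter, 1750 with a filter of 1 CPM, 1866 with limma voom and 1798 without robust dispersion. DESeq2 gave 3027 genes and 668 that differ at least 2-fold, against 373. A stricter adjusted p under 0.01 left 381 and 110 by construction. The deposited FPKM values gave 769 and 53 with a pseudocount of 1, 777 and 179 with 0.1, and 1423 and 120 for genes with a mean FPKM of at least 1. The share of called genes that were higher was 47.7% in the reported result, 39.5% with library size only, and 36.0% and 36.4% with FPKM at pseudocounts of 1 and 0.1. It was 63.7% with the leukocyte covariate, 61.3% without the 3 farthest libraries, 56.2% without control library 1 and 54.6% with DESeq2. The leukocyte covariate, which shares variance with the group, left 113 and 48. The omission of the 3 farthest libraries, with fewer samples, left 212 and 70, and the omission of chromosomes 1 and 6, with fewer genes tested, 951 and 242. Omitting single libraries gave 864 to 2774 genes, and 189 to 759 at 2-fold. The labels do not say whether the numbers in the titles pair the samples. The correlation across genes of same-numbered libraries ran from -0.28 to 0.27, and 1 library was closest to its own number. This gave no sign of pairing but does not exclude it. As a block the numbers left 755 and 192 genes. Of 102 called genes that the text or the lists name, 102 kept their call with DESeq2, 99 with limma voom, 80 with library size only, 71 with no filter, 54 with the block, 31 at an adjusted p under 0.01, 23 without the 3 farthest libraries, 12 with the leukocyte covariate, and 57 to 99 without single libraries (99, 57, 64, 72 and 64 without IL6 shRNA1 libraries 1 to 5, and 97, 65, 84, 81 and 57 without control libraries 1 to 5). None of them reversed in these settings.

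Il6 kept a positive fold change in every alternative run (0.04 without the 3 farthest libraries, 0.24 to 0.71 without single libraries) except with the leukocyte covariate, where it was -0.48. None of these fits called it. With that covariate the log2 fold changes of 5 genes that were not called also turned, to -0.18 for Il6ra, 0.12 for Mki67, -0.04 for Pecam1, -0.31 for Acta1 and -0.03 for Hbb-bs. The 15 gene lists that shift as a set became 0 with an estimated correlation, 0 with fry, 4 with the leukocyte covariate, 8 without the 3 farthest libraries, 13 without the genes of chromosomes 1 and 6, and 12 to 16 without single libraries. RLE factors and the block gave 15 each, and a filter of 1 CPM gave 14. With the block the ATF4 and unfolded protein response list gained a call (adjusted p = 0.045) and the hypoxia and glycolysis list lost it (0.059), both at the preset correlation, where an estimated one without the block gave 0.76 and 0.82. With the leukocyte covariate the direction turned for the IL-6 cytokine family (adjusted p = 0.51), interferon-stimulated genes (0.40), MHC class I antigen presentation (0.98), extracellular matrix (0.0077, now called up), the mitochondrial genome (0.40), ribosomal proteins (0.82) and muscle, fat, skin and blood (0.93). These values are at the preset correlation, and for extracellular matrix an estimated one without the covariate gave 0.99. Without the 3 farthest libraries it turned for extracellular matrix (0.36), stem cell markers (0.99) and ribosomal proteins (0.36), and without chromosomes 1 and 6 for angiogenic factors (0.92). Fibroblasts and pericytes, never called, turned with fry (0.91), RLE factors (0.94), a filter of 1 CPM (0.97), the block (0.86) and the omission of chromosomes 1 and 6 (0.82). Lists that turned when single libraries were omitted had adjusted p-values of 0.62 to 0.98 (mesenchymal and EMT genes), 0.30 to 0.93 (extracellular matrix), 0.42 to 0.89 (FOXO targets), 0.27 to 0.95 (cholesterol synthesis), 0.53 to 0.97 (angiogenic factors), 0.092 to 0.92 (mitochondrial genome), 0.02 to 0.97 (ribosomal proteins) and 0.59 to 0.98 (fibroblasts and pericytes). The 4 chromosomes called by their median became 0 with the mean in place of the median, 0 without the 3 farthest libraries, 6 at a mean of at least 10 CPM, 6 with limma, and 0 to 6 without single libraries. With the mean the chromosome 6 difference was -0.09 (adjusted exact p = 0.14) against -0.22 with the median, and that of chromosome 1 was 0.40 (0.079) against 0.32. In the other settings chromosome 1 stayed at 0.30 to 0.34 and chromosome 6 at -0.25 to -0.18. An adjusted exact p under 0.05 needs several chromosomes at the smallest p at once, which also moves these counts. Without the 3 farthest libraries that smallest p is itself larger, so the 0 called there is not evidence of a weaker shift.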

Other observations

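Apart from the rule for named genes, the genes in this part were chosen after their values were seen. Near Hoxb9 the neighbouring homeobox gene Hoxb8 (5.00 against 1.73 CPM, log2 fold change 1.53 ± 0.21 SE, adjusted p = 0.0024) and the long noncoding RNA gene Gm53 (9.40 against 0.351 CPM, 4.70 ± 0.25, adjusted p = 1.2e-05) were higher in the libraries labelled IL6 shRNA1. Igf2bp1, which starts at 95957163 on the same chromosome 11, was higher as well (2.46 ± 0.15). The other 13 genes tested between Igf2bp1 and Hoxb2 were not called. Among them were Hoxb7 at 5.86 against 5.73 CPM (adjusted p = 0.91), Hoxb6 at 7.30 against 7.32 CPM (0.99), Hoxb4 at 6.45 against 6.76 CPM (0.79) and Hoxb13 at 9.80 against 10.1 CPM (0.89). With the leukocyte score as a covariate the adjusted p of Hoxb8 was 0.088, while Hoxb9, Igf2bp1 and Gm53 were still called.

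Genes of skeletal muscle and skin were counted in the samples, which the labels describe as cells in culture and the design as tumours grown under the skin. Leukocyte genes were counted in every library of both groups (Csf1r at 100 to 327 CPM, C1qa at 112 to 565 and Ptprc at 25.3 to 140). These values argue against a culture of tumour cells alone. The myosin gene Myh4 was at 702 ± 1130 CPM in the libraries labelled IL6 shRNA1 and 56.1 ± 72.2 CPM in control (SD, n = 5; adjusted p = 0.19), and the keratin gene Krt10 at 30.4 ± 63.7 against 1.83 ± 0.42 CPM (adjusted p = 0.10). IL6 shRNA1 library 5 carried much of this, with Myh4 at 2700 and Krt10 at 144 CPM. Without it the means were 201 ± 166 CPM for Myh4 and 1.87 ± 0.48 CPM for Krt10, the latter as in control.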
